A study of Mus musculus with 187 samples.

How the data were processed

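Single mouse embryos of the FVB strain were profiled by RNA sequencing with a single-cell RNA-seq protocol and Nextera libraries, per the labels' protocols. Zygotes came from in vitro fertilisation with sperm and oocytes of animals on a control diet, were injected with RNA about 2 h later and were collected at the 2-cell stage (32 h after fertilisation) or at the 4-cell stage. The injected RNAs were small RNA isolated from sperm of males on a control or a low protein diet (0.5 ng/µl, per the file headers), a synthetic tRF-GlyGCC oligonucleotide with modified bases, a synthetic tRF-GluCTC oligonucleotide, an antisense oligonucleotide against tRF-GlyGCC, and mRNA of H3.3-GFP as the control. A tRF is a fragment of a transfer RNA. tRF-GlyGCC and tRF-GluCTC come from the glycine and glutamate tRNAs with those anticodons. Embryos positive for GFP were collected, per the labels' protocols. Collecting by GFP would need this mRNA in the other groups too, though their label of injected RNA does not name it. Groups were taken from the label of injected RNA. The end code of each title, which reads like a shared day, was taken as the batch of an embryo. In the order of their codes, the batches were given the letters A to F in the sperm RNA table, G and H in the tRF table and J to R, without O, in the 4-cell table. Batch R held GFP embryos only, batch D held 1 control embryo, and all tRF-GluCTC embryos were in batch H. The labels do not tie embryos to litters or fertilisation rounds, so p-values measure the spread between these embryos. Embryos are not tied here to males or sperm RNA preparations either, so their number per diet is unknown.

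Reads were aligned with Bowtie to mm10, per the submitters' processing notes. The versions, the counter and the annotation are not given in the sources used here. The 2 tables of 2-cell embryos hold expected counts deposited by the authors, one value per gene and embryo, with 0 shown as 0.1. From the values, 82% of those in the sperm RNA table and 81.9% of those in the tRF table were whole numbers. These tables list 8735 and 8805 genes, and the deposited gene sets already left out genes of low count. The table of 4-cell embryos holds FPKM values deposited by the authors for 23534 features, with 0 shown as 0.001. FPKM keep no library depth, so the depth of the 4-cell embryos is unknown. A further table of the authors gives their own comparison of the 4-cell groups, with group FPKM, p-value and q-value per gene, and was used only to copy values. That table names the injected group tRFGGunmod, which reads as an unmodified tRF-GlyGCC, where the labels name an antisense oligonucleotide. The authors' FPKM table of the same embryos has a column of group means headed Antisense_average, which goes with the labels. The labels were followed, and the group is called antisense here, with the identity of the injected RNA left uncertain. One line of each of the 4-cell tables was empty in the copies used here. Of 28 antisense embryos in the labels, 1 had no matching column and was not analysed here. Of the features, 8733, 8803 and 23353 matched the RefSeq gene table of GRCm38.p6 by symbol or accession, which gave the coordinates. A spreadsheet had turned some symbols into dates, and 10 of them were restored from their accessions in each table of 2-cell embryos. Among the 4-cell features 27 of these stayed unnamed, and 329 symbols occurred more than once.

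Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood test) in R 4.3.3, with batch as an additive term. The 3 groups of the tRF table shared one fit. FPKM were tested with limma 3.58.1 on log2(FPKM + 1), with trend and robust moderation and the batch term, for features with a mean of at least 5 FPKM. Fold changes of the 4-cell table are on that scale, which understates the change of low genes. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. On simulated data with the gene means and spread of these embryos, and for the 2-cell tables their library sizes, 100 genes changed 2-fold and 100 changed 4-fold among all genes tested. Of these, 64 and 98 were recovered in the low protein comparison, 18 and 71 for tRF-GlyGCC against GFP, 0 and 38 for tRF-GluCTC against GFP, 6 and 48 between the tRFs, and 83 and 98 at the 4-cell stage. Of the unchanged genes, 6, 4, 0, 4 and 8 were called in these comparisons. The simulation drew genes independently and without batch differences, unlike real embryos. At the 4-cell stage it made the changes on the log2(FPKM + 1) scale, which is a larger change in FPKM for low genes.

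Lists of genes were fixed before the data were examined, as were the groups, tests and alternatives. They cover 2-cell-stage transcripts linked to the MERVL retroelement, cytosolic ribosomal proteins, nucleolar ribosome biogenesis, oocyte-deposited maternal transcripts, heat-shock and translation genes of the major zygotic genome activation, replication-dependent histones, histone mRNA processing and Cajal bodies, the endogenous genes of histone H3.3, p53 and stress targets, interferon and RNA sensing, pluripotency and lineage, cholesterol biosynthesis, mitochondrially encoded transcripts, cumulus and granulosa cells, and sperm and testis. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. The mitochondrial list had 0 tested members. The list called heat-shock and translation here also holds other genes, among them those of tubulins, actins, RNA-binding proteins and glycolysis. As an addition chosen after seeing the data, a list score per embryo (mean log2 value of the list minus the mean over all tested genes) was compared by 100000 permutations of the group labels within batches, or by exact enumeration where there were fewer arrangements. Named genes followed a rule. It took the 10 called genes with the largest change in each direction at a mean of at least 20, or the 5 of smallest p in each direction where under 5 were called, then up to 4 members of each list by smallest p, and a fixed set of 2-cell, H3.3 and histone genes. Values are means ± SD over embryos, as CPM from the TMM-scaled counts or as FPKM. Correlations of fold changes between comparisons were set against 100 regroupings of the embryos within batches.

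Alternatives were no batch term, sample quality weights, DESeq2 1.42.0, quantile or upper quartile scaling, other filters and pseudocounts, and leaving out batches or embryos. Total counts per 2-cell embryo ran from 0.644 to 4.56 M (M for the SI prefix mega). No 2 columns were identical, and no pair of embryos correlated above 0.8937, 0.8671 or 0.9232 in the sperm RNA, tRF and 4-cell tables. Genes with near-identical copies (Zscan4, Usp17l, Tdpoz, Obox, Olfr, Vmn1r and histone families) are uncertain, since the treatment of shared reads is not given. Strand is not given either, so reads of overlapping and antisense genes cannot be told apart. Figures were drawn with matplotlib 3.10.9.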

Results

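RNA was measured in 186 single embryos. At the 2-cell stage, 42 embryos had received small RNA of control sperm and 46 small RNA of sperm from males on a low protein diet. Another 26 had received tRF-GlyGCC, 6 tRF-GluCTC and 11 GFP mRNA. At the 4-cell stage, 27 embryos had received the antisense oligonucleotide to tRF-GlyGCC and 28 GFP mRNA. The median total was 1.97 M counts with control sperm RNA (0.665 to 4.18) and 2.29 M with low protein sperm RNA (0.828 to 4.56). It was 1.89 M with tRF-GlyGCC (0.971 to 2.68), 1.81 M with tRF-GluCTC (1.26 to 2.17) and 2.08 M with GFP (0.644 to 2.34). The 4-cell embryos had a median of 10100 features at 1 FPKM or more with antisense and 10082.5 with GFP.

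The first comparison asked whether sperm small RNA of males on a low protein diet changes the 2-cell embryo relative to that of control males. By edgeR, 8 of 8721 genes were lower with low protein sperm RNA and 0 were higher, and none of the 8 belongs to a list fixed beforehand. They were the zinc finger gene Zfp488 (chromosome 14, 33967070 to 33979034, mm10), the vomeronasal receptor gene Vmn1r58, the olfactory receptor gene Olfr613 and pseudogene Olfr856-ps1, the noncoding transcripts A130077B15Rik and Gm17644, the pseudogene Gm17821, and F830016B08Rik. The last lay under the mean required for naming and was named after its values were seen. Zfp488 had 64.6 ± 51.5 CPM (SD, n = 46) with low protein RNA and 262 ± 788 CPM (n = 42) with control RNA, a log2 fold change of -1.85 ± 0.38 (SE, edgeR adjusted p = 0.0165). Olfr856-ps1 had the largest log2 fold change, -1.95 ± 0.39 (edgeR adjusted p = 0.0165), and the smallest was that of Gm17821, -1.37 ± 0.32 (edgeR adjusted p = 0.0434).

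These 8 calls rested on control replicates 26 and 22 of batch E, the control embryos of the lowest total count (0.678 and 0.665 M), where the genes averaged 3240 and 2130 CPM against at most 249 CPM in any other embryo. Without both, edgeR called 0 genes (328 at an unadjusted p under 0.05), and without either one it also called 0 (342 without replicate 26 and 345 without replicate 22). Leaving out a batch gave 14 genes without A, 15 without C and 0 without E or F. Without both, Zfp488 had 90.6 ± 65.7 CPM in the control embryos and a log2 fold change of -0.56 ± 0.22 (edgeR adjusted p = 0.999), and over all alternatives the adjusted p ran from 0.00132 to 1.0. The count at an unadjusted p under 0.05 was 348 with all embryos. Evenly spread p-values would give 436, and regrouping the embryos within batches gave a median of 258. DESeq2 called 18 genes. Sample quality weights and a block of batch and of the F number in the titles both gave 0.

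**Figure D1:**
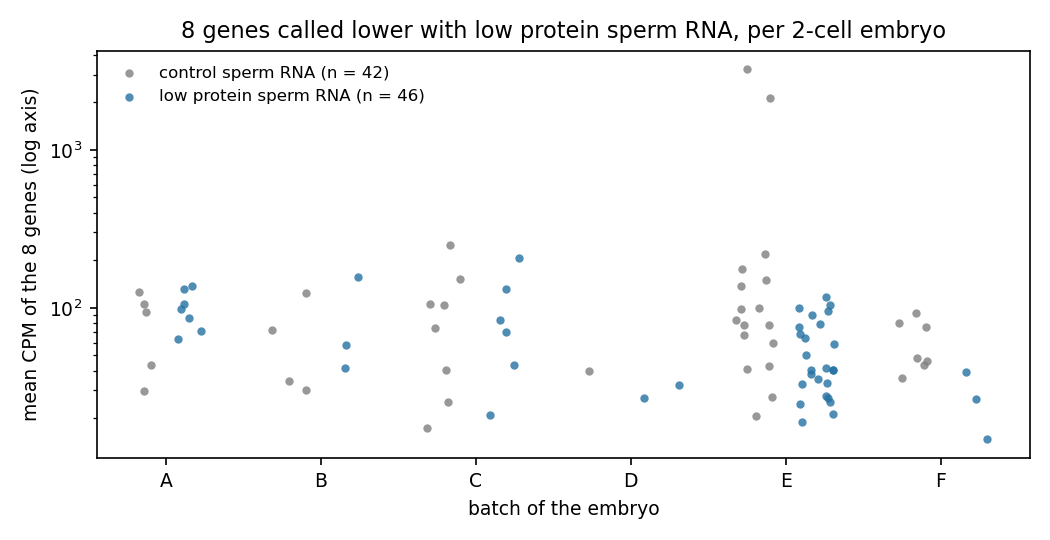
Mean CPM of the 8 genes called lower with low protein sperm RNA (log axis), with 1 point per 2-cell embryo, by batch and injected sperm RNA. The points at 3240 and 2130 CPM in batch E are control replicates 26 and 22, and every other embryo lies at or below 249 CPM.

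Of 45 transcripts of the 2-cell stage, 40 had a lower estimate and 5 a higher one with low protein sperm RNA, with a median log2 fold change of -0.25, and 0 passed when adjusted over the list alone or over all genes. The list was lower by camera (adjusted p = 1.03e-07), with adjusted p = 0.737 with an estimated correlation. Zscan4d, a marker of the 2-cell-like state, had 255 ± 243 CPM with low protein and 354 ± 300.7 CPM with control RNA (log2 fold change -0.64 ± 0.25, edgeR adjusted p = 0.959). Tcstv3 had 324 ± 240 and 517 ± 532 CPM, Tdpoz4 473 ± 319 and 630 ± 476 CPM, Zfp352 745 ± 429 and 987 ± 719 CPM, Arg2 209 ± 143 and 265 ± 175 CPM and Sp110 1646 ± 829 and 1741 ± 641 CPM. Zfp750 pointed the other way, with 62.9 ± 92.6 and 34.8 ± 26.5 CPM. The embryos' 2-cell list scores differed by -0.26 within batches (1.79 ± 1.01, n = 46, and 2.13 ± 0.95, n = 42; permutation adjusted p = 0.746). The difference was negative in 4 of 6 batches, at -1.44 in batch D, which held 1 control embryo, -1.10 in F, -0.90 in C and -0.26 in B, and 0.15 and 0.10 in A and E.

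**Figure D2:**
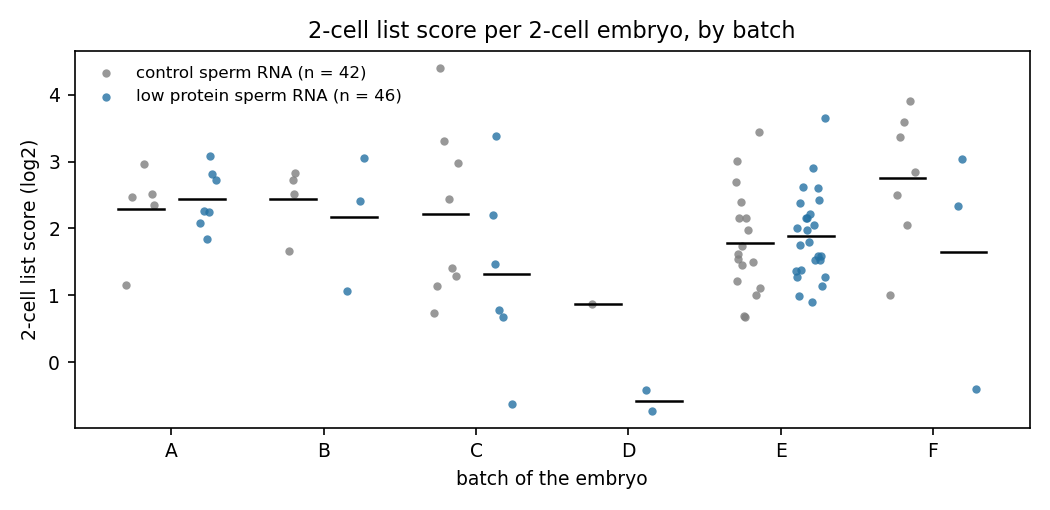
2-cell list score (log2, mean of the list minus mean of all tested genes) of each 2-cell embryo by batch, with 1 point per embryo and a line at the mean of each group in a batch. The means of the 2 groups lie within 0.15 of each other in batches A and E and are lower with low protein RNA in the other 4.

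Cholesterol biosynthesis genes, a class tied to paternal low protein diet in offspring liver, had estimates in both directions, 10 of 19 higher (camera adjusted p = 0.469). Idi1, which makes dimethylallyl diphosphate in that pathway, had 61.7 ± 56.9 CPM with low protein and 34.6 ± 23.5 CPM with control RNA (log2 fold change 0.87 ± 0.25, edgeR adjusted p = 0.313), the 1 gene of the list that passed adjusted over the list alone. Among maternal transcripts 35 of 58 had a higher estimate (camera adjusted p = 0.705), such as Bcl2l10 at 553 ± 1138 and 255 ± 178 CPM. Ribosomal protein genes divided evenly, 38 higher and 41 lower of 79 (camera adjusted p = 0.296), and nucleolar genes had 45 of 62 higher (camera adjusted p = 0.0564). H3f3b, an endogenous H3.3 gene, had 2761 ± 866 and 2722 ± 766 CPM, and H3f3a 760 ± 294 and 831 ± 293 CPM.

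The second comparison asked what the synthetic tRF-GlyGCC does to the 2-cell embryo. No gene passed: edgeR called 0 of 8804 genes, DESeq2 called 0, and sample quality weights called 1 gene lower. At an unadjusted p under 0.05 there were 284 by edgeR. Evenly spread p-values would give 440, and regrouped embryos gave a median of 211. The smallest p among lower estimates was that of Kcnq1ot1, the imprinted noncoding RNA of the Kcnq1 domain, with 66.4 ± 44.5 CPM (n = 26) against 207 ± 197 CPM with GFP (n = 11), a log2 fold change of -1.38 ± 0.35 (edgeR adjusted p = 1.0). A630089N07Rik had 37.5 ± 22.6 and 110 ± 102 CPM, and the signalling adaptor gene Crkl 59.99 ± 29.4 and 118 ± 42.3 CPM. Among higher estimates, the cytochrome b5 gene Cyb5a had 54.2 ± 42.8 and 19.7 ± 16.997 CPM, Paip2 196 ± 75.4 and 122 ± 27.1 CPM, and the spindle checkpoint gene Mad2l1 256 ± 194 and 138 ± 52.4 CPM.

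Of 79 ribosomal protein genes, 76 had a higher estimate with tRF-GlyGCC, with a median log2 fold change of 0.31 and 0 passing adjusted over the list alone. The list was higher by camera (adjusted p = 8.97e-07), with adjusted p = 0.909 with an estimated correlation. Rps23 had 110 ± 52.998 and 71.98 ± 23.3 CPM and Rpl28 39.1 ± 14.8 and 26.3 ± 6.59 CPM. Maternal transcripts had 43 of 58 higher estimates (camera adjusted p = 0.00806), with adjusted p = 0.909 with an estimated correlation, such as Omt2b at 8931 ± 3433 and 6149 ± 1631 CPM. Transcripts of the 2-cell stage had 28 of 45 lower estimates and a median log2 fold change of -0.08 (camera adjusted p = 0.00675), again with adjusted p = 0.909 with an estimated correlation. Zscan4d had 542 ± 562 and 467 ± 410 CPM, Zfp352 963 ± 1030 and 1032 ± 443 CPM, and Tdpoz2 66.9 ± 82.005 and 150 ± 105 CPM. None of the 3 lists passed the permutation of embryo scores (adjusted p = 0.900 for each). In batches G and H the score differences were 0.24 and 0.31 for ribosomal protein genes, 0.06 and 0.30 for maternal transcripts and -0.31 and -0.23 for those of the 2-cell stage.

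The endogenous H3.3 genes, whose protein the injected GFP mRNA also encodes, had 2388 ± 842 CPM with tRF-GlyGCC and 1810 ± 369 CPM with GFP for H3f3b, and 902 ± 303 and 750 ± 211 CPM for H3f3a. Neither passed (edgeR adjusted p = 1.0 for both). The tRF-GlyGCC embryos may have received the GFP mRNA as well, since embryos were collected by GFP. Reads of the H3.3 part of that mRNA may be counted on H3f3a or H3f3b in any comparison. They cannot be told here from endogenous reads.

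tRF-GluCTC, the other tRNA fragment, was compared with GFP in 6 and 11 embryos. All 6 and 5 of the GFP embryos were in batch H, and the permutation of embryo scores used only these. The means below are over all 11 GFP embryos. By edgeR 0 of 8804 genes passed, with 305 at an unadjusted p under 0.05, and DESeq2 called 1 gene lower. BC023829 had the smallest adjusted p, with 15.5 ± 15.2 CPM (n = 6) against 76.4 ± 42.3 CPM (n = 11), a log2 fold change of -2.68 ± 0.61 (edgeR adjusted p = 0.621). Rex2 had 197 ± 49.1 and 332 ± 98.5 CPM and Zfp600 164 ± 48.4 and 269 ± 77.4 CPM. Higher estimates included the phosphatase genes Cdc14a (72.1 ± 65.8 and 14.6 ± 6.49 CPM) and Ppp1ca (257 ± 102 and 131 ± 39.8 CPM) and the cytochrome c gene Cycs (373 ± 348 and 150 ± 39.6 CPM). Cyb5a, named above for tRF-GlyGCC against the same GFP embryos, had a higher estimate here too (96.99 ± 75.3 and 19.7 ± 16.997 CPM). Camera placed 3 lists higher, ribosomal proteins (53 of 79 higher, adjusted p = 0.00876), maternal transcripts (42 of 58, adjusted p = 0.0182) and heat-shock and translation genes (31 of 43, adjusted p = 0.0304), each with adjusted p = 0.656 with an estimated correlation. No member passed adjusted over the list alone, and exact permutation of the embryo scores gave adjusted p = 0.92 for each. The ribosomal list had adjusted p = 0.102 without the batch term. Transcripts of the 2-cell stage had 33 of 45 higher estimates (camera adjusted p = 0.184). Of 100 simulated 2-fold changes 0 were recovered at this group size, with genes drawn independently. The absence of calls therefore does not exclude changes of that size.

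The tRFs were also compared with each other, in one fit. edgeR called 0 of 8804 genes between tRF-GlyGCC and tRF-GluCTC, with 194 at an unadjusted p under 0.05, and DESeq2 called 1 gene higher. BC023829 had 60.4 ± 51.2 CPM with tRF-GlyGCC (n = 26) and 15.5 ± 15.2 CPM with tRF-GluCTC (n = 6), a log2 fold change of 2.17 ± 0.55 (edgeR adjusted p = 1.0). Ggta1, a glycosyltransferase gene, had 48.7 ± 31.4 and 7.93 ± 7.18 CPM, and the claudin gene Cldn6 62.7 ± 44.1 and 153 ± 113 CPM. Of 45 transcripts of the 2-cell stage 38 had a lower estimate with tRF-GlyGCC than with tRF-GluCTC, with a median log2 fold change of -0.40 and 0 adjusted over the list alone (camera adjusted p = 2.38e-05, and adjusted p = 0.667 with an estimated correlation). Heat-shock and translation genes had 27 of 43 lower estimates (camera adjusted p = 0.0183, and adjusted p = 0.667 with an estimated correlation), such as Hspa2 with 53.2 ± 39.6 and 150 ± 234 CPM. In the exact permutation of embryo scores, which used only the 16 and 6 embryos of batch H, the adjusted p was 0.399 and 0.301. The oligonucleotides also differ in chemistry, since only tRF-GlyGCC is described as carrying modified bases.

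The last comparison, at the 4-cell stage, is of embryos injected with an antisense oligonucleotide against tRF-GlyGCC, per the labels. The authors' own table of this comparison names the group tRFGGunmod, while their FPKM table heads its mean Antisense_average. The identity of the injected RNA is therefore uncertain, and neither tRF-GlyGCC nor its blocking was measured. A pair of homeobox genes of the Obox family, expressed in oocytes and early embryos, rose. Obox2 (chromosome 7, 15388851 to 15398545, mm10) had 16.3 ± 10.1 FPKM with antisense (n = 27) and 6.73 ± 4.26 FPKM with GFP (n = 28), a log2 fold change of 1.19 ± 0.22 (limma adjusted p = 0.0104). It exceeded the GFP median in 26 of 27 antisense embryos. Obox5 (chromosome 7, 15750370 to 15759274) had 35.5 ± 25.7 and 16.9 ± 8.19 FPKM, a log2 fold change of 1.03 ± 0.20 (limma adjusted p = 0.0118), and exceeded the GFP median in 25 of 27. limma called these 2 of 7237 features and none lower, with 787 at an unadjusted p under 0.05. Evenly spread p-values would give 362, and regrouped embryos gave a median of 249. Both were called with each of the 55 embryos left out in turn, where the count was 8 without antisense replicate 19, and 4 without GFP replicate 13 or 15. Without batch Q 0 features were called, and the log2 fold changes were 1.02 for Obox2 and 0.75 for Obox5, against 1.19 and 1.03 with all batches. The adjusted p was then 0.421 for Obox2 and 0.508 for Obox5, from 0.00272 at the lowest over the alternatives for both. Leaving out another batch gave 1 feature without L and 4 without M or P. The Obox genes share near-identical copies, so which of them the reads came from is uncertain.

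Without the 2 antisense embryos of low detection, replicates 19 and 9, limma called 10 features, all higher. Beside Obox2 and Obox5 these included Btg4, an adaptor of maternal mRNA deadenylation, with 67.8 ± 67.9 FPKM (n = 25) against 31.9 ± 13.9 FPKM (limma adjusted p = 0.0499), the amino acid transporter gene Slc1a5 with 28.3 ± 17.2 and 11.7 ± 5.97 FPKM (limma adjusted p = 0.0212), the phospholipase gene Pla2g4c with 13.9 ± 11.3 and 6.53 ± 4.61 FPKM (limma adjusted p = 0.0133), and the mRNA capping enzyme gene Rngtt with 31.2 ± 10 and 20 ± 6.53 FPKM (limma adjusted p = 0.0308). With all embryos Btg4 had an adjusted p of 0.141 and Rngtt one of 0.086. Slc1a5 and Pla2g4c were named after their values were seen.

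**Figure D3:**
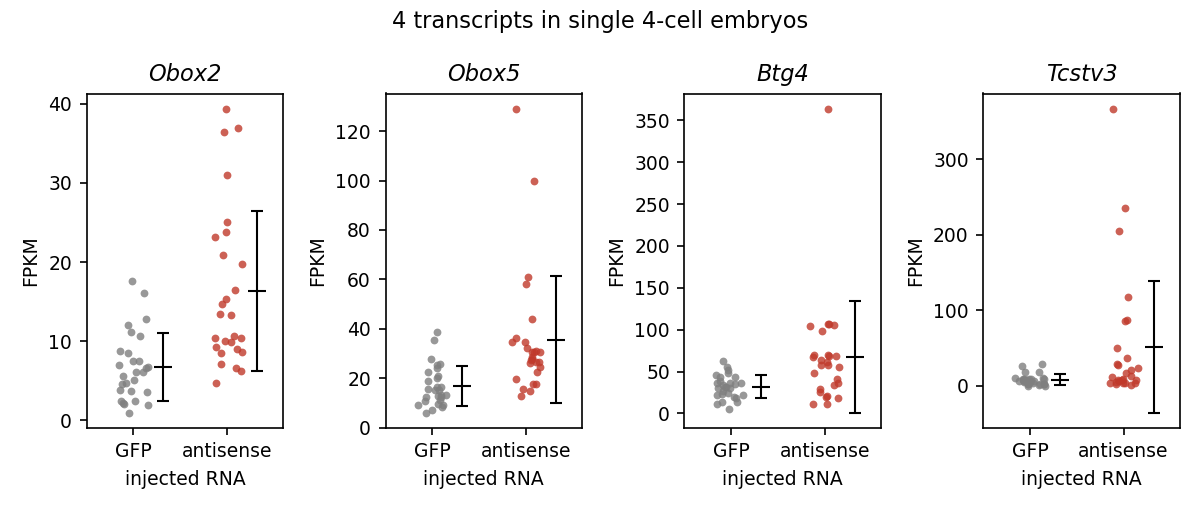
FPKM of Obox2, Obox5, Btg4 and Tcstv3 in single 4-cell embryos injected with GFP mRNA (n = 28) or the antisense oligonucleotide (n = 27), with 1 point per embryo and the mean ± SD beside each group. Obox2 has 16.3 FPKM with antisense and 6.73 with GFP, and Tcstv3 has 51.5 ± 87.02 and 7.96 ± 7.12 FPKM, where Tcstv3 and Btg4 did not pass adjusted over all features with all embryos (limma adjusted p = 0.176 and 0.141) and passed adjusted over the list alone (0.0138 and 0.00217).

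Maternal oocyte transcripts were higher as a group by camera (adjusted p = 3.91e-15) and fry (adjusted p = 0.00354), with adjusted p = 0.0516 with an estimated correlation. Of 45 tested, 42 had a higher estimate with antisense, with a median log2 fold change of 0.48, 13 passed adjusted over the list alone and 2 over all genes. Embryo list scores were 0.28 ± 0.56 (n = 27) with antisense and -0.16 ± 0.47 (n = 28) with GFP, a difference within batches of 0.44 (permutation adjusted p = 0.0051), with 23 of 27 antisense embryos above the GFP median. The difference was positive in 6 of 7 batches, from 0.26 in batch M to 0.93 in Q, and -0.24 in P. Obox1 had 18.5 ± 12.6 and 8.86 ± 5.93 FPKM (limma adjusted p = 0.141).

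Transcripts of the 2-cell stage had 33 of 37 higher estimates, with a median log2 fold change of 0.59, of which 10 passed adjusted over the list alone and 0 over all genes. The list was higher by camera (adjusted p = 4.19e-11), with adjusted p = 0.136 with an estimated correlation. Tcstv3 had 51.5 ± 87.02 and 7.96 ± 7.12 FPKM (log2 fold change 1.57 ± 0.45, limma adjusted p = 0.176), Arg2 10.9 ± 14.7 and 2.73 ± 2.73 FPKM, Zfp352 11.5 ± 19.4 and 2.39 ± 2.61 FPKM and Zscan4d 8.44 ± 9.52 and 4.18 ± 2.73 FPKM. Sp110 was level, at 1115 ± 462 and 1092 ± 491 FPKM. Members were tested at a mean of at least 5 FPKM over all embryos. Arg2, Zfp352 and Zscan4d lay under 5 FPKM with GFP and passed this filter through the antisense embryos. Members low in both groups were not tested, so the filter can raise the counts and the score. No list test was run without it. Of 27 antisense embryos 19 lay above the GFP median and 6 above the highest GFP embryo, and the score difference of 0.60 (permutation adjusted p = 0.0523) was positive in 4 of 7 batches, from 0.18 in batch L to 1.56 in Q, and -0.06, -0.32 and -0.43 in N, K and P.

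Ribosomal protein genes had 77 of 79 lower estimates with antisense, with a median log2 fold change of -0.25, of which 18 passed adjusted over the list alone and 0 over all genes. The list was lower by camera (adjusted p = 3.43e-28), with adjusted p = 0.136 with an estimated correlation. Rpl18 had 891 ± 314 and 1284 ± 573 FPKM and Rps4x 933 ± 335 and 1297 ± 605 FPKM (limma adjusted p = 0.18 for both). Embryo scores differed by -0.28 (permutation adjusted p = 0.0523), lower in 6 of 7 batches, from -0.59 in batch J to -0.17 in P, and 0.09 higher in L. Outside the list, the nucleolar protein gene Npm1 had 2159 ± 624 and 2930 ± 896 FPKM and the ribosome-associated scaffold gene Gnb2l1 409 ± 166 and 573 ± 144 FPKM (limma adjusted p = 0.141 for both). Npm1 belongs to the nucleolar list, of which 40 of 62 genes had a higher estimate (camera adjusted p = 0.542).

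Replication-dependent histone genes had 34 of 35 lower estimates, with a median log2 fold change of -0.54 and 0 passing adjusted over the list alone. The list was lower by camera (adjusted p = 2.21e-16), with adjusted p = 0.136 with an estimated correlation. Hist1h1e had 4.07 ± 5.08 and 6.05 ± 5.10 FPKM, and Hist1h2ao, whose plain means were close, 264 ± 155 and 268 ± 157 FPKM. The score difference within batches was -0.58 (permutation adjusted p = 0.0523), negative in 5 of 7 batches, from -1.88 in batch P to -0.35 in K, and 0.31 and 0.33 in L and M, while the medians of all embryos were 0.53 in both groups. Pluripotency and lineage genes (19 of 24 lower, camera adjusted p = 0.00102) and heat-shock and translation genes (33 of 43 lower, camera adjusted p = 0.00252) both had adjusted p = 0.19 with an estimated correlation, and 0 members of either passed adjusted over the list alone. Among the lineage genes, Tead4 had 101 ± 44.5 and 122 ± 31.1 FPKM. Actb, an actin gene placed in the heat-shock and translation list, had 313.4 ± 222 and 545 ± 268 FPKM.

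**Figure D4:**
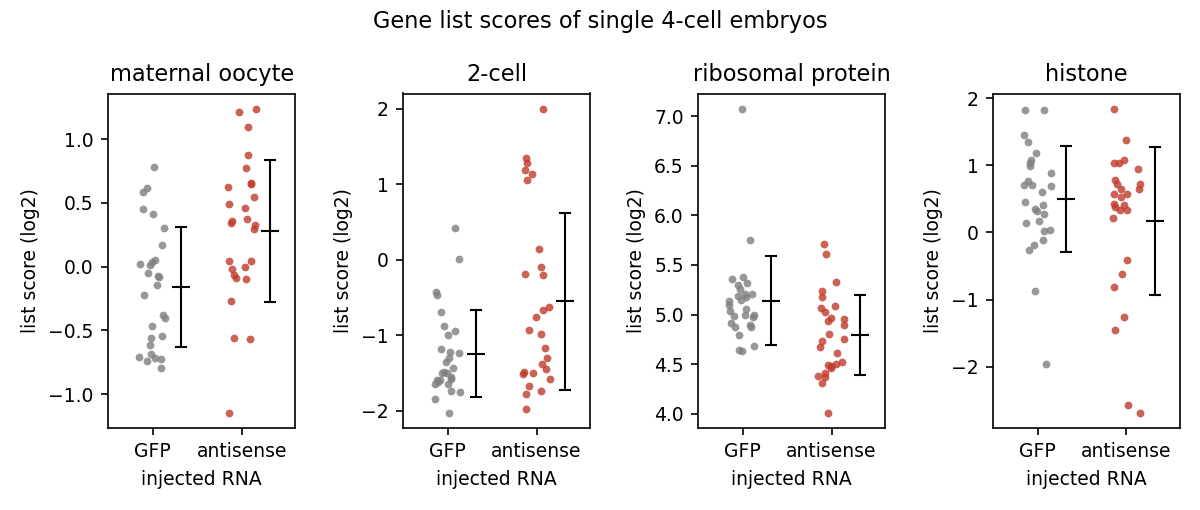
List scores (log2, mean of the list minus mean of all tested features) of single 4-cell embryos injected with GFP mRNA (n = 28) or antisense (n = 27), with 1 point per embryo and the mean ± SD beside each group. The maternal score has a mean of 0.28 with antisense and -0.16 with GFP.

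The authors' deposited table lists 72 genes as significant for this comparison, 55 higher and 17 lower in the group it names tRFGGunmod, taken here as the antisense embryos. Of 71 tested here, all 71 had the same direction and 58 an unadjusted p under 0.05, and 0 passed adjusted over all features by limma. The list was chosen on these embryos, so this direction is not independent evidence. In the 2-cell embryos, which are independent of it, 28 of 51 genes listed as higher had a higher estimate with tRF-GlyGCC, where camera ranked the set lower than other genes (p = 0.637), and 30 of 50 a lower one with low protein sperm RNA (camera p = 0.02, and p = 0.163 with an estimated correlation). Of 12 listed as lower, 8 had a lower estimate with low protein sperm RNA (camera p = 0.00507, and p = 0.0159 with an estimated correlation), and 11 a higher one with tRF-GlyGCC (camera p = 0.305). With tRF-GluCTC 39 of the 51 had a higher estimate (camera p = 0.0223, and p = 0.197 with an estimated correlation) and 8 of the 12 (camera p = 0.781). Between the tRFs 37 of the 51 had a lower estimate with tRF-GlyGCC (camera p = 0.00145, and p = 0.0744 with an estimated correlation) and 6 of the 12 (camera p = 0.702). These 8 tests were not adjusted for their number.

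Per the labels and the header of the authors' FPKM table, one comparison adds tRF-GlyGCC and another an antisense to it. Under the name in the authors' table of the comparison both would add a form of tRF-GlyGCC. Across 6054 genes tested in both, which are not independent replicates, log2 fold changes of tRF-GlyGCC and of antisense correlated with r = 0.083 and rho = 0.083 (p = 0.70 and 0.73 over 100 regroupings). Regrouped embryos gave r from -0.363 to 0.367, so an opposition or agreement within that range could not be told from chance. Each correlation with antisense also sets counts of 2-cell embryos against log2(FPKM + 1) values of 4-cell embryos. Those of tRF-GlyGCC and low protein sperm RNA correlated with r = 0.108 and rho = 0.077 over 8720 genes (p = 0.22 and 0.40), and those of low protein sperm RNA and antisense with r = 0.015 and rho = 0.027 over 6020 genes (p = 0.77 and 0.55). tRF-GlyGCC and tRF-GluCTC shared their GFP embryos and had r = 0.534, where regrouped embryos gave a median of 0.52 (p = 0.42). Their covariance was 0.124 against 0.115 in regrouped embryos, and with the GFP embryos divided between the comparisons r was -0.030 (median of 21 divisions, -0.30 to 0.20). These 4 correlations were not adjusted for their number, since none had p under 0.05.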

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

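The tests of a shared developmental course, of chance differences between embryos for the 2-cell list and for the 8 genes, of a single batch, of the 2 control embryos and of what the splits separate were chosen after the results were seen.

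With tRF-GluCTC, replicate 5 stood apart in the score of histone mRNA processing and Cajal body genes. Its score was -0.13 and those of the other 5 embryos lay between 0.36 and 0.61, a gap of 0.662 of the whole range. Of 21 measures tested in this group 1 stood apart, and chance gives about 1 in 20.

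In 4-cell embryos with antisense, camera placed maternal and 2-cell lists higher and ribosomal protein and histone lists lower, with adjusted p = 0.0516 for the maternal list and 0.136 for the other 3 with an estimated correlation. The tables argue against a few weak libraries, since without the 2 embryos of low detection the smallest of the 4 score differences, as a ratio to its full value, was 0.894 (bootstrap spread 0.109). The FPKM scaling stays open, since the smallest ratio after quantile normalization was 0.662 (spread 0.177), too near 0.5. For the 2-cell list the filter on the mean stays open too, since no list test was run without it. An earlier point of one developmental course may also account for it, and stays open, since maternal and 2-cell scores correlated with r = 0.182 over 28 GFP embryos, batch means removed (permutation p = 0.503, bootstrap interval -0.256 to 0.509, rho = 0.109, p = 0.627, and r = 0.0421 without the 2 embryos farthest out). The injected oligonucleotide itself, whose identity the labels and the authors' table give differently, remains an untested biological explanation.

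With low protein sperm RNA the 2-cell list was lower by camera, with adjusted p = 0.737 with an estimated correlation. Chance differences between embryos whose 2-cell genes vary together may account for it, since permuting the embryos' scores within batches gave p = 0.199. Library depth stays open, with a ratio of the score difference with to without the log10 total count of 0.294 (spread 0.388). A single batch stays open too, with a ratio of 0.504 without batch C (spread 0.452), 0.63 without F and 2.31 without E, and from 0.847 to 1.25 without each of the others. The diet of the males cannot be told from a difference between sperm RNA preparations, since embryos are not tied here to males or preparations.

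The 8 genes called lower with low protein sperm RNA all had lower estimates with tRF-GlyGCC too (camera p = 2.67e-06, p = 0.0372 with an estimated correlation, and fry p = 0.0208), and 3 of them passed adjusted over the 8 alone. With tRF-GluCTC 6 of the 8 had a lower estimate (camera p = 0.7). The low protein calls are consistent with 2 control embryos of low depth carrying them, since 0 of the 8 were called without these 2 control embryos. The folds then ran from -0.66 to -0.27, against -1.95 to -1.37 with all embryos, so the smaller difference ended the calls. In the tRF table chance differences between embryos may account for the pattern, since permuting the 8-gene scores within batches gave p = 0.0877. GFP replicate 10 had the lowest total count of the 2-cell embryos (0.644 M), and the 8-gene score was not tested without it. Reads from silent gene regions stay open, since 9 other olfactory and vomeronasal receptor genes had 0.0383 of the difference of the 8 genes, with a spread of 0.68.

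Chance could not be excluded for the 8 genes with low protein sperm RNA, which 6 of 100 splits of the embryos within batches matched or exceeded, the real one included. The highest other split called 166 genes, many times the real count, for a reason not identified here. That split had the 2 control embryos of low depth in different groups, and its depth difference (0.0563 in log10 total count) was reached by 18 of the 99 other splits, itself included. Of the 5 that called any gene, 2 had both embryos in one group, as did 49 of the 99, so neither measure sets these splits apart. For the counts of 0 with tRF-GlyGCC, tRF-GluCTC and between the tRFs this says nothing about chance, since 100 of 100 splits must reach 0, and the highest others called 3, 7 and 8. By the count at an unadjusted p under 0.05 chance could not be excluded there, since 29, 32 and 55 of 100 splits reached the real 284, 305 and 194, the highest others being 1710, 2082 and 1985. For the 2 genes with antisense, 1 of 100 splits, the real one, called 2. Another 3 called any gene, and the highest other called 1. A margin of 1 gene does not exclude chance. By the count at an unadjusted p under 0.05 chance could not be excluded either. There 5 of 100 splits reached the 787 with antisense, the highest other being 978.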

How the results depend on the processing

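Choices added after seeing the data were the permutation of embryo scores, the log10 total count as a covariate of the gene counts, leaving out single embryos or both control embryos, and 21 divisions of the GFP embryos, a number set after a first division gave r = -0.298. No paired analysis was possible because replicate numbers were given in accession order and name embryos without pairing them. Not run were the removal of low-detection embryos at the 2-cell stage (there were 0), pseudocounts for counts, and removal of the antisense embryo whose column is not analysed here. The cause was not tested for any change below unless stated.

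The 8 genes with low protein sperm RNA became 16 without a batch term and 18 with DESeq2, both including the 8, and 0 with sample quality weights, a block of batch and F number, the log10 total count or without both control embryos. Leaving out one batch or one control embryo gave 0 to 15, with 0 without batches E or F. The counts of 0 became 1 with quality weights for tRF-GlyGCC, and 1 with DESeq2 for tRF-GluCTC and between the tRFs. The 2 genes with antisense became 10 without low-detection embryos, 1 with upper quartile scaling and 1 at a mean of at least 20. Obox2 lay under that mean and was not tested there. Leaving out one batch or embryo gave 0 (batch Q) to 8 (antisense replicate 19), with 4 without GFP replicates 13 or 15. No batch term and quality weights each gave 3, within 1.5 times.

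Camera calls lost with an estimated correlation, with fry and with permuted embryo scores had these adjusted p. The 2-cell list had 0.737, 0.863 and 0.746 with low protein RNA. All 3 lists of tRF-GlyGCC (2-cell, ribosomal, maternal) had 0.909, 0.993 and 0.9. All 3 of tRF-GluCTC (ribosomal, maternal, heat-shock) had 0.656, 0.892 and 0.92. Between the tRFs both lists had 0.667 and 0.916, and 0.399 (2-cell) and 0.301 (heat-shock). With antisense, 2-cell, ribosomal and histone lists had 0.136 with an estimated correlation, and 0.0676, 0.0756 and 0.0823 with fry. Lineage and heat-shock lists had 0.19 and 0.188, and these 5 lists 0.0523 with permuted scores. The maternal list had 0.0516 with an estimated correlation only. Quantile normalization gave 0.833 for the maternal list of tRF-GlyGCC, 0.691 for the maternal and heat-shock lists of tRF-GluCTC and 0.198 for heat-shock between the tRFs. No batch term gave 0.102 for ribosomal genes of tRF-GluCTC. Over the pairs of a called list and an alternative, 48 lost the call, 33 kept it and 0 reversed. With one 4-cell embryo left out the differences kept their sign. The histone difference of -0.58 became -0.45 (permutation p = 0.0596, from 0.0303) without antisense replicate 10, and the lineage difference -0.21 (p = 0.0554, from 0.0272) without antisense replicate 4. The heat-shock difference became -0.09 (p = 0.0612, from 0.0314) without GFP replicate 1. The maternal permutation p was 0.00124 in the refit nearest 0, without GFP replicate 12.

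Correlations of fold changes reversed sign for tRF-GlyGCC with antisense (-0.0165 without a batch term, -0.0125 with quantile normalization), low protein RNA with antisense (-0.0121 with quantile normalization) and tRF-GlyGCC with tRF-GluCTC (-0.0303 with divided GFP embryos, whose construction removes the shared controls).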

Other observations

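Groups of genes without a call are given as values. With antisense, 10 of 18 genes of histone mRNA processing had a higher estimate (camera adjusted p = 0.268), led by Usp1, a deubiquitinase of DNA repair, at 100 ± 29.8 and 78.9 ± 28.97 FPKM. p53 and stress genes had 7 of 13 higher (camera adjusted p = 0.542), and 2 passed adjusted over the list alone, Ppp1r15a, which reverses eIF2 phosphorylation, at 110 ± 106 and 57.1 ± 28.7 FPKM and Mdm2, the p53 ubiquitin ligase, at 50.2 ± 23.7 and 33.1 ± 17.3 FPKM. Nucleolar genes had 40 of 62 higher (camera adjusted p = 0.542) and cholesterol genes 7 of 14 (camera adjusted p = 0.268). H3f3a had 889 ± 218 and 1001 ± 348 FPKM and H3f3b 1100 ± 650 and 1029 ± 289 FPKM.

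Of the interferon and RNA sensing list, 7 members were tested with low protein sperm RNA (5 lower, camera adjusted p = 0.469), and 4 at the 4-cell stage, where Irf3 had 13.9 ± 7.35 FPKM with antisense and 10.6 ± 4.89 with GFP (limma adjusted p = 0.63). Among markers of cumulus and granulosa cells 4 passed the filter on the mean, and reads of all 4 were present in both groups. This does not tell transcripts of the embryo from those of adhering cells. The other markers of the list lay under the filter or were absent and were not examined. Gja1 had 161 ± 57.8 and 178 ± 51.1 FPKM and Amhr2 114 ± 44.1 and 100 ± 27.1 FPKM with antisense and GFP. Of the sperm and testis list, Odf2 had 17.7 ± 7.61 and 13.7 ± 5.80 FPKM and Ldhc 11.7 ± 9.40 and 10.03 ± 9.52 FPKM. None of these passed.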
